A study of Homo sapiens with 79 samples.

How the data were processed

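RNA from HCT116 cells with wild-type p53 (WT, 40 arrays) and from a derivative without p53 (KO, 39 arrays) had been labelled from an oligo-dT primer and hybridised to two-colour 70-mer oligonucleotide arrays. Per the labels, Cy3 was untreated RNA of the same genotype and Cy5 was RNA of cells exposed to NO, H2O2, HU or hypoxia. No dye swap and no untreated array is among the 79. The deposited values are taken as log2 ratios of the 2 channels. The authors state no scanner software, background correction, normalisation, log base or direction of the ratio. The array medians lay between -0.31 and 0.065 as deposited and the SD of an array between 0.16 and 0.94. Values from -9.04 to 8.83 exceed 4.82, the log10 of a 16-bit scanner's range, which excludes log10, while a natural log is not excluded. No signal, background or depth is given.

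The deposited file holds 21794 rows, of which 17434 have 1 gene symbol, 75 several and 4285 none, and 17409 have an Entrez identifier in the RefSeq gene annotation. Left out were 396 rows of 12 accessions printed 10 times or more, a rule for control rows chosen after seeing the file. Each array was centred on its median, and probes with a value on at least 50% of the arrays and on at least 1 array of each condition were tested, 20147 in all (16351 with 1 symbol, for 14541 genes).

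The rule on direction fixed before the data were examined took the ratio as Cy5 over Cy3, to be checked by whether HIF targets lay above 0 in 24 h hypoxia, and gave no direction if this failed. It failed: the list median lay below 0 on 8 of 8 such arrays. After the data were seen this rule was set aside, all values were multiplied by -1, and directions are given as likely. With the sign as deposited, counts of rises and falls change places. The check by correlation gave a median r across probes of 0.52 between arrays of a condition and 0.16 between conditions, 0.64 within late conditions and 0.28 within 1 h conditions. The lowest, -0.66, was between KO H2O2 24 h replicate 3 and KO NO 1 h replicate 4, and the lowest within a condition was -0.45. Probes are not independent replicates. The 4 arrays in the 2 pairs below -0.30 within a condition were WT HU 1 h replicates 1 and 3 and KO NO 1 h replicates 2 and 4.

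Tests used limma 3.58.1 with statmod 1.5.0 and data.table (version 1.17.8) in R 4.3.3. The model held 8 means of genotype and stress, and genotype by time slot (1 h, the middle time of 4, 8 or 12 h, and 24 h), with the 24 conditions as a random block (consensus correlation 0.307). No label says that arrays of a condition came from separate cultures, so p values rest on a spread between hybridisations and conditions that may be technical. Moderated 2-sided contrasts were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. The 17 comparisons were WT minus KO over all stresses and in each stress, an F test of its difference between stresses, the response of each genotype to each stress against 0, and 24 h against 1 h in WT, in KO and between them. A response against 0 holds the dye effect and leaves out the spread of the untreated control. WT minus KO cancels the dye effect and not the 2 untreated references, and the F test and the tests of time cancel both where a reference is common.

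The 15 gene lists fixed before the data were examined were tested by cameraPR with a preset correlation of 0.01, one probe per gene, adjusted over 240 tests of list and comparison. They were p53 targets, mitosis and G2/M, S phase and replication, DNA repair, HIF targets, NRF2 and oxidative stress, heat shock, ATF4 and unfolded protein response, immediate early, NF-kB and inflammation, interferon, cholesterol synthesis, metallothionein and zinc, ribosomal proteins, and markers of fibroblasts and leukocytes. Some genes are members of more than 1 list. No passing list had a median, mean and test of different sign, or a median that turned without centring or after scaling, and these settings moved the median of all genes by 0.078 at most. Estimated correlations and fry were alternatives.

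Named genes followed a rule fixed beforehand. It took per comparison the 10 largest rises and 10 largest falls past the test with 1 symbol, then the 4 largest members of each passing list, then genes fixed for the stress, up to 30, and fixed genes beyond the 30 were added. Not every fixed gene is reported. A gene is given by its probe with values on the most arrays. Errors of fitted values are SE, and errors of condition means are SD over hybridisations.

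The pipeline was tested on simulated data with 200 of 20147 probes changed. For WT minus KO over all stresses it made 193 calls, 6 false. It recovered 89% of changes of 0.5 and 98% of changes of 1 on the log2 scale. For WT minus KO in NO it made 128 calls, 4 false, with 32% and 92%. For 24 h against 1 h in WT it made 141, 5 false, with 42% and 94%. WT NO gave 174 calls, 6 false, and KO hypoxia 172, 9 false. These shares describe simulated data and were not tested on these arrays.

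Alternatives were condition means, arrays as independent replicates, no centring, scaling to one median absolute deviation, filters of 80% of arrays or none, array weights, the 5 blocks of consecutive hybridisation numbers as a term, trended and robust moderation, a 1.5-fold cut-off, 24 h alone, each stress against the other 3, and each array left out in turn. Added after seeing the data were later times minus 1 h, no 1 h conditions, no low-correlation arrays, control rows kept, and differences within blocks. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.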

Results

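Messenger RNA levels were measured in HCT116, a human colon carcinoma cell line, in its form with wild-type p53 (WT) and in a derivative without p53 (KO). Cells were exposed to 1 mM Sper/NO, a nitric oxide donor (NO), to 0.1 mM hydrogen peroxide (H2O2), to 1.5 mM hydroxyurea, an inhibitor of ribonucleotide reductase (HU), or to hypoxia. RNA was taken after 1, 8 and 24 h of NO, after 1, 4 and 24 h of H2O2, and after 1, 12 and 24 h of HU and of hypoxia. Each of the 79 two-colour arrays set exposed cells in Cy5 against untreated cells of the same genotype in Cy3. The 40 WT arrays comprised 9 for NO, 11 for H2O2, 10 for HU and 10 for hypoxia, and the 39 KO arrays comprised 10, 11, 9 and 9. A genotype, stress and time (24 conditions) was hybridised 2 to 5 times, and whether these hybridisations used separate cultures is not given in the sources used here. Between 16186 and 21091 of the 21794 rows had a value on an array, and the number of arrays limits the precision. The series' title names p53 and inflammatory stress.

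Values are log2 ratios with their standard error (SE), and a value in parentheses after a gene is its log2 ratio. The log base is not stated. Base 2 was assumed, and a natural log would make every fold larger. The sign was also settled from the data. As deposited, the median of 45 known targets of the hypoxia-inducible factor (HIF) lay below 0 on 8 of 8 arrays of 24 h hypoxia (-0.73 to -1.64), and HMOX1 lay below 0 on 19 of 19 NO arrays. The rule fixed beforehand would then have given no direction. It was set aside after the data were seen, and all values were multiplied by -1. "Rose" and "higher" therefore mean the side of 0 on which HIF targets lay in 24 h hypoxia, likely exposed over untreated cells, and the rise of HIF targets in hypoxia is no independent evidence. With the sign as deposited every rise below is a fall of the same size. Not all arrays went together: 104 of 3081 pairs of arrays correlated below -0.30 across probes, each with a 1 h array in the pair, and 2 of them within a condition.

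The first question was which genes responded differently with and without p53. Here and below, higher or lower in WT compares ratios of likely exposed over untreated RNA, since no array set WT against KO RNA. On average over the 4 stresses and 3 times, known p53 targets lay higher in WT than in KO cells. Among genes past the test, the WT ratio stood highest above the KO ratio for CCN1 (2.01-fold, log2 ratio 1.01 ± 0.15), an immediate early gene for a matrix protein. PLK2 (1.88-fold, log2 ratio 0.91 ± 0.11), a stress-induced kinase, and SESN1 (1.77-fold, log2 ratio 0.82 ± 0.075), a sestrin induced by p53, came next. PLK3 (0.69), PHLDA3 (0.65), TP53INP1 (0.62), PPM1D (0.61), AEN (0.59), THBS1 (0.57) and TRIAP1 (0.56) completed the 10 largest rises. Of 81 measured p53 targets 26 were higher in WT and 0 lower, and 55 and 0 when adjusted within the list (median 0.22). Adjusted p was 9.47e-89 and adjusted p = 8.24e-14 with an estimated correlation. Among p53 targets named beforehand, MDM2 (0.41), the ubiquitin ligase of p53, and GDF15 (0.47), a stress cytokine, were higher. The cyclin-dependent kinase inhibitor CDKN1A (0.32), TP53I3 (0.33), BBC3 (0.28) and FAS (0.20) did not pass the test. BTG2 and CA9 were not analysed here.

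The ratio was lower in WT than in KO cells for 4 transcription factors of the circadian clock and its output. They were DBP (2.05-fold lower, log2 ratio -1.04 ± 0.12), NR1D1 (-0.62), NR1D2 (-0.60) and TEF (-0.44). The ratio was also lower for RGS2 (1.7-fold lower, log2 ratio -0.76 ± 0.10), a regulator of G protein signalling, the kinetochore proteins CENPF (-0.66) and CENPE (-0.44), and ETV1 (-0.35). The mitosis and G2/M list was lower in WT, with 2 of 41 members lower and 15 adjusted within the list (median -0.17), and the next members in size were DLGAP5 (-0.38) and HMMR (-0.37), which did not pass. Adjusted p was 2.96e-27 and adjusted p = 0.0467 with an estimated correlation. CENPF and CENPE belong to a set of 7 genes that lay above 0 in KO HU arrays from 1 h on (mean 1.00 at 1 h, 1.02 at 12 h and 1.01 at 24 h). The immediate early list was higher in WT with CCN2 (0.56) past the test and DUSP5 (0.43) and NR4A2 (0.41) short of it, and 2 of 26 members passing, 4 adjusted within the list (median 0.12). Adjusted p was 3.53e-09 and adjusted p = 0.0702 with an estimated correlation. Also higher as lists were cholesterol synthesis (median 0.10, 0 of 20 passed) and ribosomal proteins (median 0.034, 0 of 49 passed). Adjusted p was 4.13e-05 and 0.0315 for these in order. Adjusted p = 0.359 and 0.816 with an estimated correlation. Their largest members were STARD4 (0.34), INSIG1 (0.29), MSMO1 (0.23), SCD (0.19), RPL10 (0.14), RPL10A (0.11) and RPL28 (0.11).

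In all, 62 of 20147 probes passed an adjusted p of 0.05 (limma), 54 higher and 8 lower in WT, for 55 genes, and 952 passed an unadjusted 0.05. The p53 target median was higher in WT in 11 of the 12 pairs of conditions, though hardly at 1 h (0.018 to 0.069 in WT, 0.008 to 0.039 in KO, lower in WT in hypoxia), and within the 5 blocks of consecutive hybridisation numbers it differed by 0.24, 0.18, 0.071, 0.52 and 0.38. The mitosis list was lower in 10 of 12 pairs, not in NO at 1 and 8 h, and by -0.087, -0.035, -0.26, -0.20 and -0.22 within the blocks, and the immediate early list differed by 0.014, -0.008, 0.23, 0.32 and 0.39. The count was 13 from condition means, 1102 with arrays as independent replicates, 135 (82 higher, 53 lower) after scaling the arrays to one spread and 259 (131 higher, 128 lower) with array weights, and from 24 h alone the majority turned (551 higher, 877 lower). In the difference between the later times and 1 h, which cancels an untreated reference common to both, 6 probes passed, and DBP (0.029), NR1D1 (0.13), NR1D2 (0.45), TEF (0.28) and CDKN1A (-0.023) changed sign. The other probes of THBS1 (0.064 and 0.074), TEF (-0.11 and 0.016) and ETV1 (-0.43 and -0.35) did not pass.

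**Figure D1:**
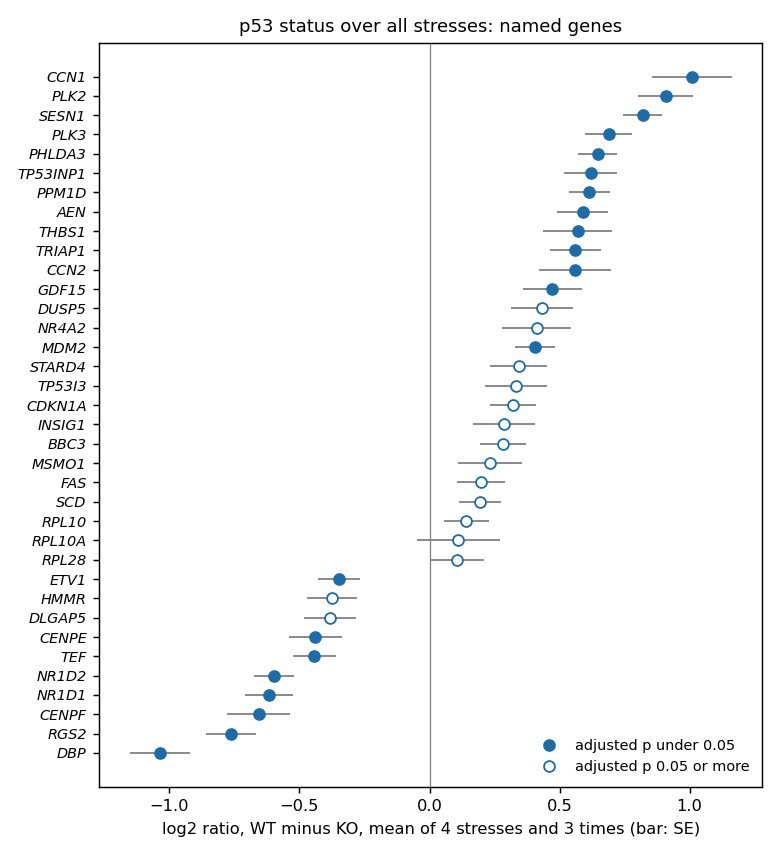
Log2 ratio of WT minus KO (x axis) of each named gene (y axis) as the mean of 4 stresses and 3 times, with the SE as bars, from 40 WT and 39 KO arrays. Filled points passed an adjusted p of 0.05, from CCN1 at 1.01 down to DBP at -1.04, and open points did not.

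**Figure D2:**
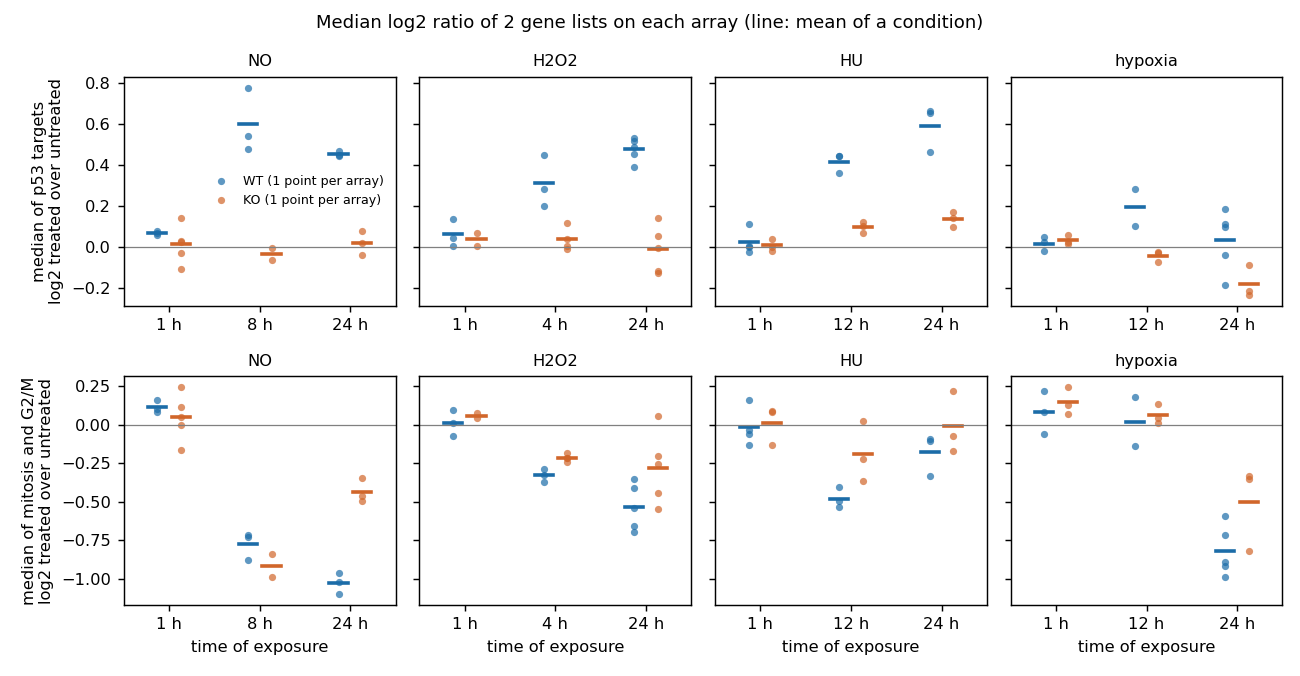
Median log2 ratio, in the likely direction of exposed over untreated cells (y axis), of p53 targets (top) and of mitosis and G2/M genes (bottom) against time (x axis) for the 4 stresses. Each point is 1 array and each line the mean of a condition, and the p53 target mean in WT lay above that in KO in 11 of 12 pairs of conditions, hardly so at 1 h.

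The same WT minus KO comparison was made per stress. Under NO CCN1 (2.87-fold, log2 ratio 1.52 ± 0.31), PLK2 (1.22), GDF15 (1.11), PHLDA3 (1.08), SESN1 (2.11-fold, log2 ratio 1.08 ± 0.15), PLK3 (0.93), PPM1D (0.79), MDM2 (0.76), SUSD6 (0.73) and ATG12 (0.65) were higher in WT, and RGS2 (1.92-fold lower, log2 ratio -0.94 ± 0.20) was lower. CLIP4 (0.60), outside the naming rule and named after its values were seen, was higher. Of 81 p53 targets 7 were higher, 44 adjusted within the list (median 0.39). Adjusted p was 5.39e-56 and adjusted p = 9.04e-09 with an estimated correlation. CDKN1A (0.50), TP53I3 (0.62), BBC3 (0.54) and FAS (0.35) did not pass. The immediate early list was higher, with CCN1 alone past the test and 5 of 26 adjusted within the list (median 0.29), and CCN2 (1.20), DUSP5 (0.86) and MAFF (0.69) did not pass. Adjusted p was 3.19e-11 and adjusted p = 0.0363 with an estimated correlation. Higher lists with 0 members passing over all probes were cholesterol synthesis (median 0.24, 0 of 20, 2 up adjusted within the list) and NRF2 and oxidative stress (median 0.15, 0 of 28 passed). Adjusted p was 2.45e-08 and 0.00677 for these in order. Adjusted p = 0.16 and 0.64 with an estimated correlation. Their largest members were INSIG1 (0.78), STARD4 (0.66), MSMO1 (0.48), HMGCS1 (0.42), AKR1B10 (0.64), UGDH (0.40), GCLM (0.34) and GPX1 (0.31). Lower lists were mitosis and G2/M (median -0.16, 0 of 41 passed) and S phase and replication (median -0.10, 0 of 41 passed), with RACGAP1 (-0.43), DLGAP5 (-0.43), BUB1 (-0.35), KIF23 (-0.30), CCNE1 (-0.41), SLBP (-0.39), CCNE2 (-0.33) and FEN1 (-0.30) as largest members. Adjusted p was 3.57e-08 and 0.000551 for these in order. Adjusted p = 0.416 and 0.765 with an estimated correlation. The mitosis median was lower in WT at 24 h (-1.03 against -0.44) and higher at 1 h (0.12 against 0.049) and 8 h (-0.78 against -0.92). Of the oxidative stress and immediate early genes fixed beforehand, HMOX1 (0.27), TXNRD1 (0.038), FOS (0.11) and EGR1 (0.53) did not pass, and TXNRD1 changed sign after scaling (-0.010). The test gave 14 probes (13 higher, 1 lower) and 567 at an unadjusted 0.05, from 9 WT and 10 KO arrays. The count was 0 from condition means and against the other 3 stresses, 4 after scaling, and 31 with the block of hybridisation numbers as a term. From 24 h alone the majority turned (112 higher, 152 lower), and another ATG12 probe (0.54) did not pass.

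Under H2O2 the sestrin SESN1 (1.82-fold, log2 ratio 0.86 ± 0.15) was higher in WT, and the clock genes DBP (2.44-fold lower, log2 ratio -1.29 ± 0.23), NR1D1 (-0.94) and NR1D2 (-0.89) were lower. The clock genes and TEF already differed by a mean of -0.96 at 1 h (-1.11 at 24 h). The p53 targets were higher as a list, with 1 member past the test and 6 adjusted within the list (median 0.25), and PLK2 (0.65), PPM1D (0.59), TP53INP1 (0.56), CDKN1A (0.41), MDM2 (0.46), GDF15 (0.47), TP53I3 (0.51), BBC3 (0.11) and FAS (0.24) did not pass. Adjusted p was 1.81e-52 and adjusted p = 2.73e-08 with an estimated correlation. The other higher list was cholesterol synthesis (median 0.12, 0 of 20 passed), with SCD (0.43), STARD4 (0.34), INSIG1 (0.28) and MVD (0.26). Adjusted p was 3.85e-07 and adjusted p = 0.222 with an estimated correlation. Lower lists were mitosis and G2/M (median -0.14, 0 of 41, 1 down adjusted within the list), S phase and replication (median -0.046, 0 of 41 passed), ATF4 and unfolded protein response (median -0.11, 0 of 31 passed) and immediate early (median -0.063, 0 of 26 passed). Adjusted p was 2.83e-13, 0.0233, 3.75e-05 and 0.000498 for these in order. Adjusted p = 0.246, 0.816, 0.359 and 0.359 with an estimated correlation. Their largest members were CENPF (-0.82), CENPE (-0.46), DLGAP5 (-0.34), HMMR (-0.33), PCNA (0.25), MCM5 (-0.18), GINS2 (-0.15), MCM3 (-0.15), ASNS (-0.52), STC2 (-0.34), DDIT3 (-0.29), TRIB3 (-0.26), JUN (-0.46), KLF2 (-0.34), GEM (-0.29) and FOS (-0.25). CENPF and CENPE lay above 0 in KO H2O2 arrays too, where the set of 7 genes had means of 0.72 at 1 h, 0.49 at 4 h and 0.58 at 24 h. HMOX1 (-0.068), TXNRD1 (-0.14), GCLM (-0.10) and EGR1 (0.13) did not pass. The test gave 4 probes (1 higher, 3 lower) and 150 at an unadjusted 0.05, from 11 WT and 11 KO arrays. The count was 0 from condition means and against the other 3 stresses, and the majority turned after scaling (16 higher, 12 lower), from 24 h alone (384 and 181), with independent replicates (56 and 25) and without the 1 h conditions (13 and 7).

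Under HU the sulfatase SULF2 (2.19-fold, log2 ratio 1.13 ± 0.18) was higher in WT, and the clock genes DBP (3.07-fold lower, log2 ratio -1.62 ± 0.23), NR1D1 (2.31-fold lower, log2 ratio -1.21 ± 0.18) and NR1D2 (-0.93) and the ubiquitin ligase TRIM2 (-0.82) were lower. No p53 target passed over all probes, while 10 did adjusted within the list and the list was higher (median 0.25), with PLK2 (0.87), TP53INP1 (0.81), PPM1D (0.71) and SESN1 (0.66) as largest members. Adjusted p was 4.52e-30 and adjusted p = 6.81e-05 with an estimated correlation. CDKN1A (0.060), MDM2 (0.36), GDF15 (-0.31), TP53I3 (0.38), BBC3 (0.13) and FAS (0.22) did not pass, and CDKN1A changed sign after scaling (-0.045). The other higher list was NF-kB and inflammation (median 0.066, 0 of 25 passed), with IL1A (0.49), IL1B (0.45), CCL20 (0.39) and PTGS2 (0.32). Adjusted p was 0.0294 and adjusted p = 0.246 with an estimated correlation. Lower lists were mitosis and G2/M (median -0.17, 0 of 41, 3 down adjusted within the list), NRF2 and oxidative stress (median -0.12, 0 of 28 passed), ATF4 and unfolded protein response (median -0.15, 0 of 31 passed) and cholesterol synthesis (median -0.18, 0 of 20 passed). Adjusted p was 1.58e-14, 0.000685, 3.56e-08 and 7.50e-06 for these in order. Adjusted p = 0.204, 0.504, 0.193 and 0.315 with an estimated correlation. Their largest members were CENPF (-1.08), CENPE (-0.87), HMMR (-0.58), KIF14 (-0.49), SLC7A11 (-0.50), GCLC (-0.40), ME1 (-0.29), AKR1B10 (0.27), ASNS (-0.69), DDIT3 (-0.45), CARS1 (-0.43), TRIB3 (-0.41), HMGCS1 (-0.49), CYP51A1 (-0.32), IDI1 (-0.28) and MSMO1 (-0.26), and CENPF and CENPE are among the 7 genes that lay near 1.00 in KO HU arrays. Of the genes fixed for HU, RRM1 (0.16), RRM2 (0.091), CCNE2 (0.41), CCNB1 (-0.30) and PLK1 (-0.18) did not pass. The test gave 5 probes (1 higher, 4 lower) and 408 at an unadjusted 0.05, from 10 WT and 9 KO arrays. The count was 0 from condition means and against the other 3 stresses, 81 (30 higher, 51 lower) after scaling, 8 (4 and 4) without WT hypoxia 24 h replicate 4, and 21 (14 higher, 7 lower) without the 1 h conditions, where the majority turned. Another probe of IDI1 lay at 0.026.

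Under hypoxia CCN1 (3.07-fold, log2 ratio 1.62 ± 0.31), the nuclease AEN (2.05-fold, log2 ratio 1.04 ± 0.20), the kinase PLK3 (0.97) and the histone deacetylase HDAC2 (0.77) were higher in WT, and the other 2 probes past the test had no symbol. The p53 targets were higher with 2 members past the test, 6 up and 1 down adjusted within the list (median 0.14), and PLCL2 (-1.53) and PLK2 (0.90) did not pass. Adjusted p was 2.30e-10 and adjusted p = 0.0702 with an estimated correlation. Nor did CDKN1A (0.32), MDM2 (0.041), GDF15 (0.62), TP53I3 (-0.18), SESN1 (0.68), PPM1D (0.38), BBC3 (0.36) and FAS (-0.015). The immediate early list was higher with 1 of 26 past the test and 3 adjusted within the list (median 0.32), and DUSP5 (1.00), NR4A2 (0.87) and DUSP1 (0.58) did not pass. Adjusted p was 1.72e-14 and adjusted p = 0.0109 with an estimated correlation. Higher lists with 0 members passing were cholesterol synthesis (median 0.13, 0 of 20 passed) and ribosomal proteins (median 0.078, 0 of 49 passed), with MSMO1 (0.58), STARD4 (0.53), SQLE (0.39), DHCR7 (0.34), RPL10 (0.34), RPL23 (0.27), RPL28 (0.24) and RPL35A (-0.23). Adjusted p was 5.40e-05 and 0.000636 for these in order. Adjusted p = 0.359 and 0.743 with an estimated correlation. The lower list was mitosis and G2/M (median -0.19, 0 of 41 passed), with CENPF (-0.45), MKI67 (-0.43), KIF11 (-0.42) and CCNA2 (-0.42). Adjusted p was 6.40e-08 and adjusted p = 0.434 with an estimated correlation. The HIF targets VEGFA (0.23), LDHA (-0.052), BNIP3 (-0.12) and NDRG1 (-0.055) did not pass. The test gave 6 probes (5 higher, 1 lower) and 837 at an unadjusted 0.05, from 10 WT and 9 KO arrays. The count was 34 without WT hypoxia 24 h replicate 4, 12 without replicate 5 of that condition or replicate 1 or 3 of WT hypoxia 1 h, 11 without KO hypoxia 12 h replicate 1, and 0 from condition means, after scaling and against the other 3 stresses. The majority turned from 24 h alone (373 higher, 865 lower) and with independent replicates (346 and 479). A second FAS probe lay at 0.091.

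Whether the WT minus KO difference itself differed between the 4 stresses was tested for every probe. The limma F test passed 0 of 20147 probes, against 250 at an unadjusted 0.05. It passed 663 with independent replicates, 8 without the 1 h conditions, 2 with array weights and 1 after scaling, so a gene named for 1 stress is not shown to differ from its value in another.

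The next question was how each genotype responded to each stress. NO raised haem oxygenase, HMOX1 (10.3-fold, log2 ratio 3.36 ± 0.23), most in WT cells, and its level was 1.30 ± 0.089 (SD, n = 3) at 1 h, 4.77 ± 0.54 (SD, n = 3) at 8 h and 4.03 ± 0.56 (SD, n = 3) at 24 h. CCN1 (7.44-fold, log2 ratio 2.90 ± 0.22), DUSP5 (1.96), GDF15 (1.95), GADD45B (1.94), CCN2 (1.92), PPP1R15A (1.89), THBS1 (1.76), SVOP (1.73) and GCLM (1.72), a subunit of the glutathione-synthesising ligase, rose next. The largest falls were the replication-dependent histone genes H3C12 (4.23-fold lower, log2 ratio -2.08 ± 0.25), H2AC14 (-1.49) and H3C10 (-1.29). Others were DDX46 (-1.31), MAT2A (-1.26), DLGAP5 (-1.25), DBP (-1.23), KIF18A (-1.21), DENND5B (-1.16) and FAM83D (-1.14). Histone values throughout are of oligo-dT-primed RNA only. The p53 targets rose, 40 of 81 up and 2 down, 49 and 3 adjusted within the list (median 0.33), with PLK2 (1.70), GADD45A (1.58) and SFN (1.58). Adjusted p was 3.49e-30 and adjusted p = 6.81e-05 with an estimated correlation. Mitosis and G2/M genes fell, 33 of 41, 37 adjusted within the list (median -0.56), with CCNB1 (-0.97), CCNF (-0.92) and KIF23 (-0.88). Adjusted p was 6.30e-29 and adjusted p = 0.0363 with an estimated correlation. So did 7 of 41 S phase genes, also 7 adjusted within the list (median -0.17), with CDC7 (-0.75), SLBP (-0.61), GMNN (-0.54) and GINS1 (-0.53). Adjusted p was 0.000636 and adjusted p = 0.765 with an estimated correlation. NRF2 and oxidative stress genes rose, 18 of 28, 21 adjusted within the list (median 0.54), including the thioredoxin reductase TXNRD1 (0.76). Adjusted p was 1.25e-26 and adjusted p = 0.00237 with an estimated correlation. So did 21 of 26 immediate early genes against 1 that fell, 21 and 1 adjusted within the list (median 0.78), including FOS (1.35) and EGR1 (1.09). Adjusted p was 7.73e-28 and adjusted p = 5.03e-05 with an estimated correlation. Also higher were hypoxia HIF targets (median 0.28, 16 up and 1 down of 45, 22 up and 1 down adjusted within the list), ATF4 and unfolded protein response (median 0.10, 6 up of 31, 9 up adjusted within the list), NF-kB and inflammation (median 0.18, 6 up of 25, also adjusted within the list), cholesterol synthesis (median 0.13, 4 up of 20, 7 up and 1 down adjusted within the list) and ribosomal proteins (median 0.077, 3 up of 49, 2 up adjusted within the list). Adjusted p was 4.02e-08, 0.000323, 0.00113, 0.0463 and 0.015 for these in order. Adjusted p = 0.359, 0.452, 0.0502, 0.756 and 0.804 with an estimated correlation.

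In KO cells NO again raised HMOX1 (8.54-fold, log2 ratio 3.10 ± 0.23) most, from 1.48 ± 0.43 (SD, n = 5) at 1 h to 3.88 ± 0.29 (SD, n = 2) at 8 h and 4.19 ± 0.080 (SD, n = 3) at 24 h. GADD45B (1.76), PPP1R15A (1.54), GCLM (1.38), CCN1 (1.37), SFN (1.32), TSC22D3 (1.30), SETMAR (1.26), SRXN1 (1.26) and ABHD4 (1.24) rose next, and H3C12 (3.57-fold lower, log2 ratio -1.84 ± 0.25), H2AC14 (-1.42), KITLG (-1.08), MAT2A (-1.08), H3C10 (-1.08), DDX46 (-1.07), HELLS (-1.02), RIF1 (-1.01) and H2AC17 (-0.90) fell most. Mitosis genes fell, 23 of 41 with 1 up, 33 and 1 adjusted within the list (median -0.38), with DLGAP5 (-0.82), CCNB1 (-0.81), CENPE (-0.76) and PLK1 (-0.74). Adjusted p was 6.12e-16 and adjusted p = 0.172 with an estimated correlation. HIF targets rose, 13 of 45 with 1 down, 22 and 1 adjusted within the list (median 0.29), with SLC2A3 (1.19), NDRG1 (1.08), ALDOC (1.03) and PDK1 (0.84). Adjusted p was 1.36e-08 and adjusted p = 0.346 with an estimated correlation. NRF2 and oxidative stress genes rose, 14 of 28, 19 adjusted within the list (median 0.32), with the ferritin chain FTL (1.15) and TXNRD1 (0.72). Adjusted p was 3.51e-21 and adjusted p = 0.01 with an estimated correlation. Also higher were ATF4 and unfolded protein response (median 0.086, 3 up of 31, also adjusted within the list), immediate early (median 0.47, 13 up and 1 down of 26, 17 up and 1 down adjusted within the list) and NF-kB and inflammation (median 0.22, 4 up of 25, also adjusted within the list), with ATF4 (0.65), SLC3A2 (0.47) and FOS (1.24) past the test and EGR1 (0.56) short of it. Adjusted p was 0.0168, 1.65e-12 and 0.000916 for these in order. Adjusted p = 0.7, 0.0225 and 0.0472 with an estimated correlation. The p53 target list did not pass (median -0.008).

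NO changed 2503 probes in WT (1023 up, 1480 down, 9 arrays) and 2198 in KO (514 up, 1684 down, 10 arrays). Both genotypes shared 371 rises and 915 falls with 0 opposite, against 26.1 and 123.7 by chance. Dye effects are common to both. The counts were 877 and 442 from condition means, and the WT majority turned there (484 up, 393 down), with a 1.5-fold cut-off (265 and 190) and against the other 3 stresses (444 and 225). Without KO NO 8 h replicate 1 or replicate 2, which make up that condition, the KO count was 1140 or 1362, and with the block of hybridisation numbers as a term the majority turned in both genotypes (2397 up and 1392 down in WT, 1271 and 957 in KO) and DDX46 lay at 0.061 in KO. Other probes did not pass or went the other way for THBS1 (0.17 and -0.29), DDX46 (-0.079 in WT, -0.10 in KO), DENND5B (-0.15 in WT), KITLG (-0.16 in KO) and RIF1 (-0.38 in KO).

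**Figure D3:**
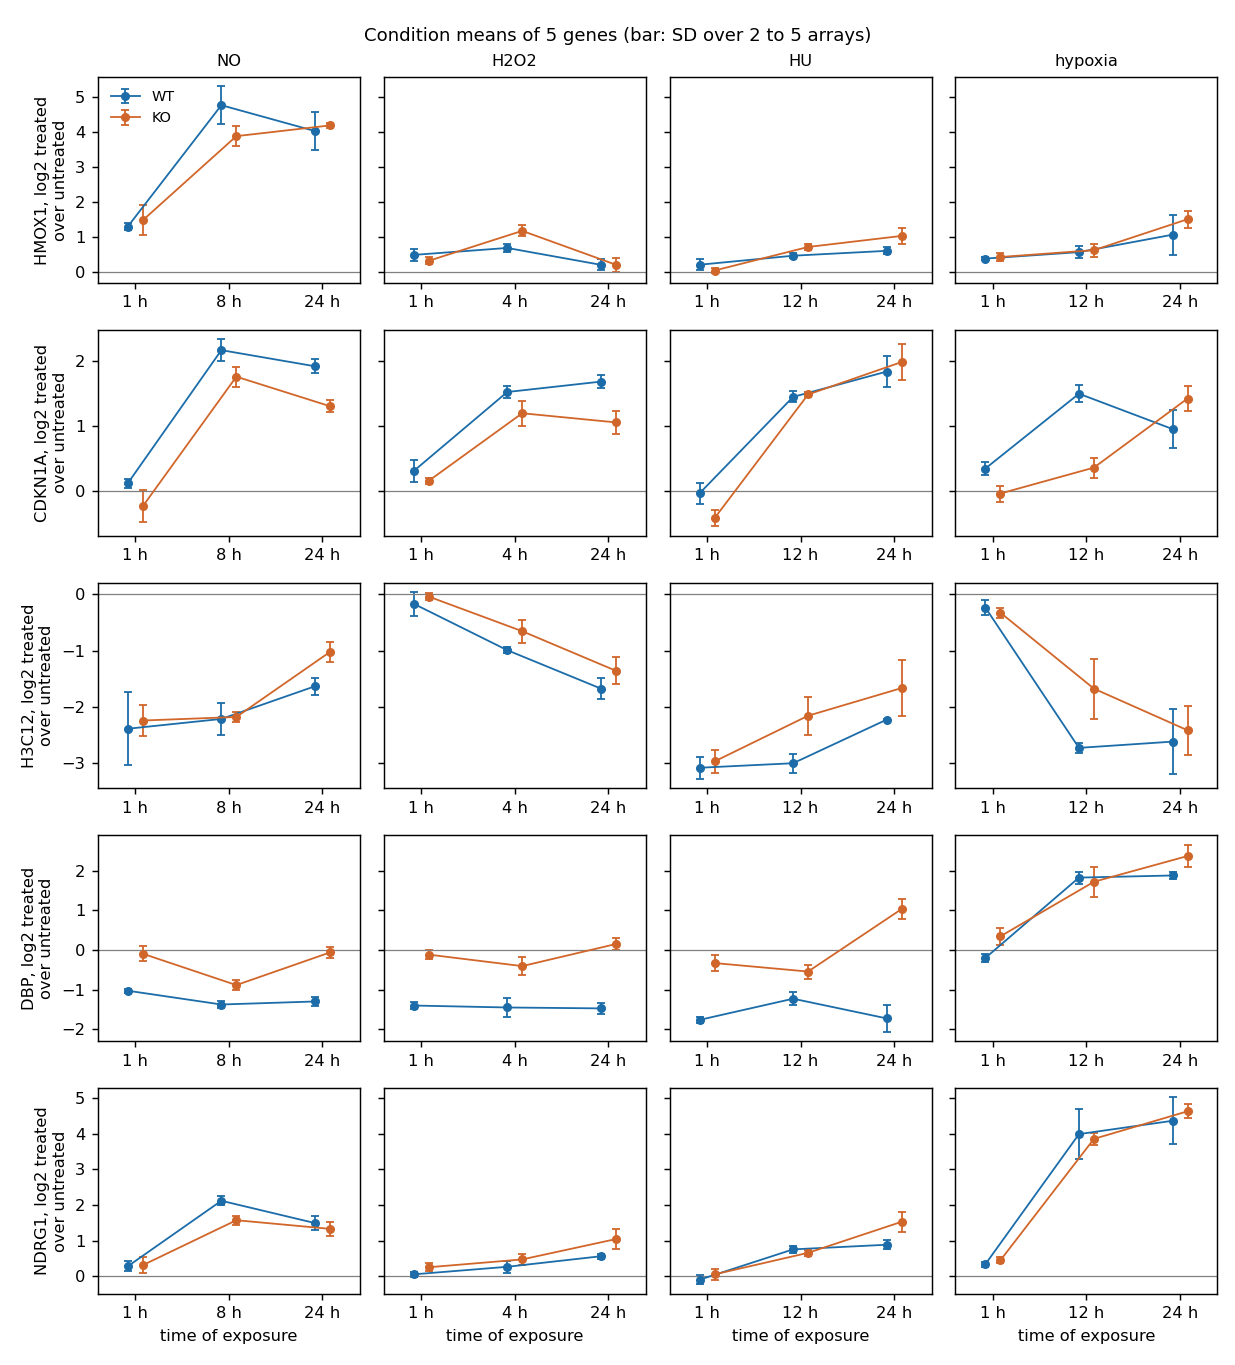
Mean log2 ratio, in the likely direction of exposed over untreated cells (y axis), of 5 genes against time (x axis) for the 4 stresses in WT and KO cells, with the SD over 2 to 5 arrays as bars. HMOX1 reached 4.77 after 8 h of NO in WT, H3C12 lay at -3.08 after 1 h of HU in WT, and NDRG1 reached 4.63 after 24 h of hypoxia in KO.

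H2O2 raised p53 targets in WT cells. Among genes past the test GDF15 (2.75-fold, log2 ratio 1.46 ± 0.16), CDKN1A (2.25-fold, log2 ratio 1.17 ± 0.12), SFN (0.95), PLK2 (0.93), GADD45A (0.90), CCN1 (0.86), PMAIP1 (0.80), SESN1 (0.77), SERPINB5 (0.74) and MAFF (0.73) were the 10 largest rises. CDKN1A stood at 1.68 ± 0.094 (SD, n = 5) at 24 h. The largest falls past the test were DBP (2.73-fold lower, log2 ratio -1.45 ± 0.16), DDX46 (-1.09), H3C12 (-0.98), PER2 (-0.97), TEF (-0.67), DLGAP5 (-0.62), KIF23 (-0.56), BUB1 (-0.55), FAM83D (-0.53) and NR1D2 (-0.53). Of 81 p53 targets 20 rose, 44 adjusted within the list (median 0.28). Adjusted p was 3.85e-56 and adjusted p = 9.04e-09 with an estimated correlation. Mitosis genes fell, 4 of 41 and 22 adjusted within the list (median -0.27), with AURKA (-0.50) short of the test. Adjusted p was 1.25e-26 and adjusted p = 0.0481 with an estimated correlation. Immediate early genes rose, 2 of 26 and 9 adjusted within the list (median 0.28), while FOS (0.59) and EGR1 (0.36) did not pass. Adjusted p was 1.29e-15 and adjusted p = 0.00744 with an estimated correlation. Also lower were S phase and replication (median -0.11, 0 of 41 passed) and heat shock (median -0.15, 0 of 19, 2 down adjusted within the list), with GINS2 (-0.34), SLBP (-0.28), MCM6 (-0.26), POLE2 (-0.25), HSPA1B (-0.65), HSPA8 (-0.52), DNAJB1 (-0.44) and HSPA1A (-0.42) short of the test. Adjusted p was 0.00015 and 3.75e-05 for these in order. Adjusted p = 0.743 and 0.304 with an estimated correlation. Also higher were ATF4 and unfolded protein response (median 0.066, 0 of 31 passed) and NF-kB and inflammation (median 0.076, 2 up of 25, also adjusted within the list), with PPP1R15A (0.60) short of the test. Adjusted p was 0.00354 and 0.00419 for these in order. Adjusted p = 0.567 and 0.0964 with an estimated correlation. HMOX1 (0.43), TXNRD1 (0.13) and GCLM (0.037) did not pass.

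In KO cells DDIT4 (2.27-fold, log2 ratio 1.19 ± 0.25), GDF15 (1.98-fold, log2 ratio 0.99 ± 0.16), JUN (0.94), CEP290 (0.83), ASNS (0.82), UPP1 (0.81), GADD45A (0.81), CDKN1A (0.76), FOSB (0.76) and STC2 (0.75) rose most, and CDKN1A stood at 1.05 ± 0.18 (SD, n = 5) at 24 h. ZNF827 (1.56-fold lower, log2 ratio -0.64 ± 0.10), SCD (-0.54), the lipogenic transcription factor SREBF1 (-0.47), PURA (-0.44), RABL6 (-0.41), AIMP1 (-0.40), PDE4C (-0.37), TMEM135 (-0.36) and ANKMY2 (-0.34) fell most among genes past the test. Immediate early genes rose, 3 of 26 and 15 adjusted within the list (median 0.43), with FOS (0.84) and EGR1 (0.23) short of the test. Adjusted p was 7.77e-31 for this list and adjusted p = 1.41e-05 with an estimated correlation. ATF4 and unfolded protein response genes rose, 2 of 31 and 10 adjusted within the list (median 0.17), with DDIT3 (0.75) and TRIB3 (0.61) short of the test. Adjusted p was 7.78e-12 and adjusted p = 0.081 with an estimated correlation. The p53 list passed as higher, yet its median was 0.001, 41 of 81 above 0, 3 up, 7 adjusted within the list. BTG1 (0.61) did not pass. Adjusted p was 0.00247 and adjusted p = 0.492 with an estimated correlation. The mitosis list was lower (median -0.14), yet 0 of 41 members fell and 1, CENPF (0.75), rose, 0 and 2 adjusted within the list, and CENPE (0.56), AURKA (-0.36) and CCNF (-0.36) did not pass. Adjusted p was 7.62e-06 for this list and adjusted p = 0.539 with an estimated correlation. Also lower were heat shock (median -0.16, 0 of 19 passed) and cholesterol synthesis (median -0.092, 1 down of 20, 2 down adjusted within the list), with HSPA1B (-0.61), HSPA1A (-0.46), DNAJB1 (-0.41) and HSPA8 (-0.31) short of the test, and higher was NF-kB and inflammation (median 0.075, 1 up of 25, also adjusted within the list). Adjusted p was 0.000187, 0.000207 and 0.00462 for these in order. Adjusted p = 0.359, 0.416 and 0.0964 with an estimated correlation. HMOX1 (0.49), TXNRD1 (0.27) and GCLM (0.13) did not pass.

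H2O2 changed 73 probes in WT (50 up, 23 down) and 43 in KO (31 up, 12 down), 11 arrays each, with 8 rises and 0 falls shared against 0.1 and 0 by chance. After scaling the majority turned in both (587 up and 955 down in WT, 631 and 816 in KO), as with array weights, with independent replicates, from 24 h alone and, in KO, without the 1 h conditions, the counts were 5 and 1 from condition means, 40 in WT without WT H2O2 1 h replicate 3, and 28 or 27 in KO without KO H2O2 1 h replicate 1 or 4 h replicate 4. Against the other 3 stresses many named genes turned sign in both genotypes, among them GDF15 (-0.16 in WT and in KO), CCN1 in WT (-1.03) and DDIT4 in KO (-0.48). With the block term STC2 lay at -0.20, and other probes of DDX46 (-0.044), TEF (-0.27 and -0.061) and RABL6 (0.011) did not pass.

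Under HU in WT cells the histone genes H3C12 (6.96-fold lower, log2 ratio -2.80 ± 0.25), H2AC14 (4.3-fold lower, log2 ratio -2.10 ± 0.26), H3C10 (-1.75), H2AC17 (-1.44), H1-4 (-1.24), H4C1 (-1.18), H2BC14 (-1.16) and H2BC17 (-0.93) were 8 of the 10 largest falls, with DBP (-1.56) and the collagen COL4A6 (-1.04), and H3C12 stood at -3.08 ± 0.20 (SD, n = 4) at 1 h. The cyclin CCNE2 (2.29-fold, log2 ratio 1.20 ± 0.22), GDF15 (1.11), CDKN1A (1.07), SFN (1.05), SULF2 (1.04), CA2 (1.04), CCN1 (1.03), SERPINB5 (1.02), LGALS7 (0.93) and WNT9A (0.92) rose most. Of 81 p53 targets 30 rose, 46 up and 1 down adjusted within the list (median 0.35), with TP53INP1 (0.89). Adjusted p was 4.63e-35 and adjusted p = 1.41e-05 with an estimated correlation. Mitosis genes fell, 12 of 41 and 19 adjusted within the list (median -0.23), with PLK1 (-0.85), DLGAP5 (-0.83), CCNB1 (-0.74) and AURKA (-0.72). Adjusted p was 5.13e-12 for this list and adjusted p = 0.301 with an estimated correlation. S phase genes rose, 5 of 41 and 6 adjusted within the list (median 0.034), with CCNE1 (0.54) and the ribonucleotide reductase subunits RRM2 (0.54) and RRM1 (0.39), and PCNA (0.42) short of the test. Adjusted p was 0.0119 for this list and adjusted p = 0.809 with an estimated correlation. Immediate early genes rose, 3 of 26, 6 up and 1 down adjusted within the list (median 0.17), with CCN2 (0.81) and MAFF (0.57). Adjusted p was 0.000636 for this list and adjusted p = 0.367 with an estimated correlation. Also higher were NF-kB and inflammation (median 0.12, 1 up of 25, 3 up adjusted within the list), interferon (median 0.080, 2 up of 24, 4 up adjusted within the list) and cholesterol synthesis (median 0.13, 2 up of 20, 4 up adjusted within the list). Adjusted p was 0.00589, 0.0241 and 0.00765 for these in order. Adjusted p = 0.107, 0.301 and 0.6 with an estimated correlation.

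In KO cells H3C12 (4.81-fold lower, log2 ratio -2.27 ± 0.25), H2AC14 (4.26-fold lower, log2 ratio -2.09 ± 0.26), H3C10 (-1.66), H1-4 (-1.40), DDX46 (-1.34), H2AC17 (-1.34), H4C1 (-1.22), H2BC14 (-1.02), TUBA4B (-0.97) and COL4A6 (-0.94) fell most, and H3C12 stood at -2.97 ± 0.20 (SD, n = 3) at 1 h. GDF15 (2.68-fold, log2 ratio 1.42 ± 0.16) rose most. Large coiled-coil proteins of the Golgi and the centrosome, GOLGB1 (1.23), AKAP9 (1.11), GOLGA4 (1.08) and CEP290 (0.99), the linker DST (1.07) and the kinetochore proteins CENPE (1.16) and CENPF (0.96) rose too, with CDKN1A (1.01) and CDKN1C (0.92). These 7 genes had means of 1.00 at 1 h, 1.02 at 12 h and 1.01 at 24 h, and 2 other probes of DST lay at -0.20 and -0.091. Of 81 p53 targets 6 rose and 1 fell, 10 and 2 adjusted within the list (median 0.076), with SFN (0.55) and GADD45A (0.54). Adjusted p was 0.000358 for this list and adjusted p = 0.384 with an estimated correlation. The DNA repair list was higher with 1 of 26 up, 3 up and 1 down adjusted within the list (median 0.066), with MRE11 (0.37) past the test and ATM (0.37), XRCC5 (-0.35) and RAD51AP1 (0.33) short of it. Adjusted p was 0.0421 for this list and adjusted p = 0.769 with an estimated correlation. HIF targets were higher, 1 of 45 and 3 adjusted within the list (median 0.11), with BHLHE40 (0.70) past the test and ALDOC (0.79), NDRG1 (0.75) and DDIT4 (0.68) short of it. Adjusted p was 0.0049 for this list and adjusted p = 0.747 with an estimated correlation. Also higher were NRF2 and oxidative stress (median 0.14, 2 up of 28, 4 up adjusted within the list), ATF4 and unfolded protein response (median 0.24, 5 up of 31, 12 up adjusted within the list), immediate early (median 0.14, 1 up of 26, 4 up adjusted within the list) and cholesterol synthesis (median 0.27, 7 up of 20, 11 up adjusted within the list), and lower was heat shock (median -0.086, 1 down of 19, 2 down adjusted within the list). Adjusted p was 6.38e-06, 8.54e-11, 0.00703, 5.13e-12 and 0.041 for these in order. Adjusted p = 0.345, 0.0964, 0.527, 0.0656 and 0.705 with an estimated correlation. Of the genes fixed for HU, CCNE2 (0.79) rose, PLK1 (-0.67) fell, and RRM1 (0.23), RRM2 (0.45) and CCNB1 (-0.44) did not pass.

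HU changed 807 probes in WT (390 up, 417 down, 10 arrays) and 523 in KO (322 up, 201 down, 9 arrays), with 124 rises and 106 falls shared and 0 opposite, against 6.2 and 4.2 by chance. The counts were 47 and 39 from condition means and 2929 and 2906 after scaling. The KO majority turned after scaling (1405 up, 1501 down), from 24 h alone (1593 and 2239), from condition means (18 and 21) and without KO HU 24 h replicate 3 (163 and 173, 336 in all). The WT majority turned with the block term (1121 up, 390 down), from condition means (36 and 11), with a 1.5-fold cut-off (76 and 42), against the other 3 stresses (419 and 238), with trended and robust moderation (334 and 296) and without the low-correlation arrays (332 and 317). Another DDX46 probe lay at 0.12.

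Hypoxia changed the most probes. In WT cells DDIT4 (10.9-fold, log2 ratio 3.45 ± 0.26), an inhibitor of mTOR signalling, BHLHE40 (8.18-fold, log2 ratio 3.03 ± 0.20), NDRG1 (7.59-fold, log2 ratio 2.92 ± 0.24), DUSP5 (2.56), the aldolase ALDOC (2.55), the clock gene PER1 (2.52), HILPDA (2.51), the prolyl hydroxylase subunit P4HA1 (2.47), DDIT3 (2.41) and KDM3A (2.39) rose most, and NDRG1 went from 0.34 ± 0.075 (SD, n = 3) at 1 h to 4.37 ± 0.65 (SD, n = 5) at 24 h. NTSR1 (4.01-fold lower, log2 ratio -2.004 ± 0.21), ITPRIPL2 (-1.98), the chaperone HSPA1B (-1.95), HPS6 (-1.93), LRR1 (-1.91), H3C12 (-1.87), RRS1 (-1.82), DCBLD2 (-1.79), JADE2 (-1.78) and DDX46 (-1.74) fell most. HIF targets rose, 36 of 45 with 1 down, the same adjusted within the list (median 0.95), among them VEGFA (0.95), LDHA (0.55) and BNIP3 (1.81), a direction that rests on the choice of sign. Adjusted p was 1.43e-27 for this list and adjusted p = 0.0212 with an estimated correlation. The p53 targets moved both ways, 25 up and 17 down, 26 and 17 adjusted within the list (median 0.066), with GDF15 (1.81), BTG1 (1.70), KITLG (-1.52) and GADD45A (1.46). Adjusted p was 0.00235 for this list and adjusted p = 0.492 with an estimated correlation. Mitosis genes fell, 21 of 41 with 4 up, 22 and 4 adjusted within the list (median -0.33), with the proliferation marker MKI67 (-1.62), KIF11 (-0.91), STMN1 (-0.88) and CCNF (-0.82). Adjusted p was 0.0147 for this list and adjusted p = 0.788 with an estimated correlation. S phase genes fell, 34 of 41, also 34 adjusted within the list (median -0.71), with CCNE2 (-1.52) and CHAF1A (-1.25). Adjusted p was 1.34e-10 for this list and adjusted p = 0.416 with an estimated correlation. Also higher were ATF4 and unfolded protein response (median 0.38, 19 up and 2 down of 31, 21 up and 2 down adjusted within the list), immediate early (median 0.97, 20 up and 1 down of 26, also adjusted within the list), cholesterol synthesis (median 0.14, 7 up and 5 down of 20, also adjusted within the list) and ribosomal proteins (median 0.21, 23 up and 2 down of 49, also adjusted within the list), and lower were DNA repair (median -0.33, 1 up and 18 down of 26, 1 up and 20 down adjusted within the list) and heat shock (median -0.39, 1 up and 11 down of 19, 1 up and 12 down adjusted within the list). Adjusted p was 1.59e-09, 3.68e-17, 0.0191, 3.12e-06, 0.000663 and 0.00374 for these in order. Adjusted p = 0.135, 0.00399, 0.691, 0.552, 0.534 and 0.504 with an estimated correlation.

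In KO cells DDIT4 (14.3-fold, log2 ratio 3.84 ± 0.26), NDRG1 (7.89-fold, log2 ratio 2.98 ± 0.24), ALDOC (2.79), BHLHE40 (2.66), KDM3A (2.41), the cyclin CCNG2 (2.399), HILPDA (2.34), PER1 (2.33), the mitophagy receptor BNIP3L (2.22) and P4HA1 (2.20) rose most, and NDRG1 went from 0.45 ± 0.086 (SD, n = 3) at 1 h to 4.63 ± 0.20 (SD, n = 3) at 24 h. The ribosome biogenesis factor RRS1 (4.23-fold lower, log2 ratio -2.08 ± 0.19), DDX46 (-1.98), HSPA1B (-1.80), HPS6 (-1.74), NTSR1 (-1.63), MRTO4 (-1.58), CTPS1 (-1.57), POP1 (-1.56), LRR1 (-1.54) and SAMHD1 (-1.53) fell most. HIF targets rose, 33 of 45 with 1 down, 34 and 1 adjusted within the list (median 0.78), with VEGFA (0.71), LDHA (0.60) and BNIP3 (1.93). Adjusted p was 1.22e-30 for this list and adjusted p = 0.0116 with an estimated correlation. S phase genes fell, 34 of 41 and 35 adjusted within the list (median -0.68), with CCNE2 (-1.40), GINS2 (-1.26), CDC25A (-1.16) and CHAF1A (-1.09). Adjusted p was 2.54e-11 for this list and adjusted p = 0.384 with an estimated correlation. DNA repair genes fell, 16 of 26 with 1 up, the same adjusted within the list (median -0.32), with XRCC2 (-1.04), XRCC3 (-0.93), ATR (-0.91) and RAD51C (-0.88). Adjusted p was 0.00244 for this list and adjusted p = 0.586 with an estimated correlation. Heat shock genes fell, 12 of 19 with 2 up, 13 and 2 adjusted within the list (median -0.48), with HSPA1A (-1.26) and DNAJA1 (-1.18). Adjusted p was 0.0032 for this list and adjusted p = 0.492 with an estimated correlation. Also higher were ATF4 and unfolded protein response (median 0.38, 21 up and 2 down of 31, 22 up and 2 down adjusted within the list), immediate early (median 0.60, 16 up and 3 down of 26, also adjusted within the list) and ribosomal proteins (median 0.15, 19 up and 4 down of 49, 21 up and 4 down adjusted within the list). Adjusted p was 5.37e-09, 4.02e-08 and 0.0008 for these in order. Adjusted p = 0.155, 0.0964 and 0.747 with an estimated correlation.

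Hypoxia changed 8322 probes in WT (3061 up, 5261 down, 10 arrays) and 8077 in KO (3102 up, 4975 down, 9 arrays), with 2120 rises and 4233 falls shared and 1 opposite, against 471.3 and 1299.1 by chance. The counts were 4905 and 4726 after scaling, and the share of rises in KO moved from 38.4% to 49.1% without centring. Other probes did not pass or went the other way for DDX46 (0.10 in WT, 0.16 in KO), BTG1 (0.17 in WT), KITLG (-0.25 in WT), STMN1 (0.30 in WT), KDM3A (0.29 in KO) and ATR (0.18 in KO). DDX46 fell by 1 probe alone in each stress, so a dye effect on that probe stays open.

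**Figure D4:**
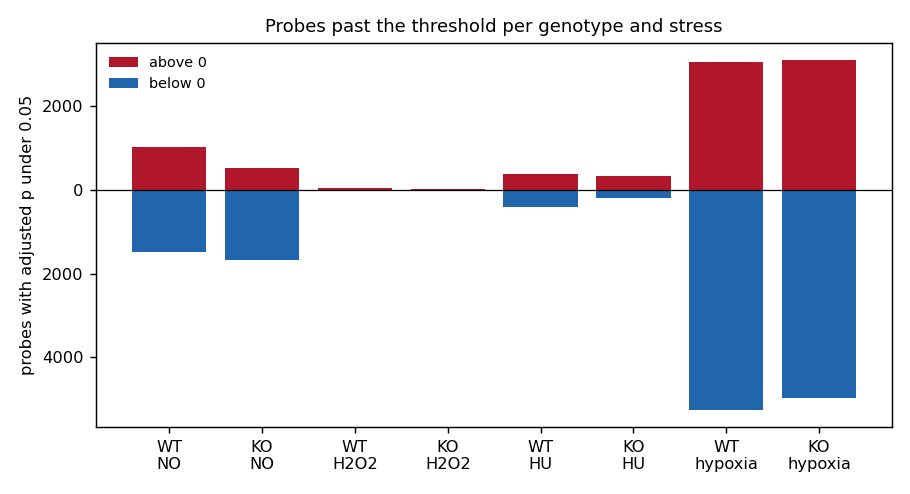
Number of probes (y axis) with an adjusted p under 0.05 above 0 (red, upwards) and below 0 (blue, downwards) in each genotype and stress (x axis), in the likely direction of exposed over untreated cells. Counts ran from 43 for KO H2O2 to 8322 for WT hypoxia.

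How the response changed with time was asked by 24 h against 1 h over the 4 stresses, which cancels dye and a reference common to both times. In WT cells ALDOC (3.63-fold, log2 ratio 1.86 ± 0.33), GDF15 (3.26-fold, log2 ratio 1.70 ± 0.19), NDRG1 (1.70), SAT1 (1.47), CYP4F2 (1.42), CDKN1A (2.63-fold, log2 ratio 1.40 ± 0.15), RAI2 (1.35), BACC1 (1.32), TCF21 (1.29) and CYP4F3 (1.24) rose most. The nucleolar protein NOP56 (3-fold lower, log2 ratio -1.58 ± 0.17), TCF7L2 (-1.44), MRTO4 (-1.43), the cyclin CCNB1 (-1.42), TUBB (-1.42), H2AX (-1.41), MRPL20 (-1.36), HSPE1 (-1.33), KITLG (-1.33) and MCMBP (-1.32) fell most. The p53 targets rose, 35 of 81 with 6 down, 42 and 6 adjusted within the list (median 0.34), with TNFRSF10D (1.17). Adjusted p was 3.37e-13 for this list and adjusted p = 0.0305 with an estimated correlation. Mitosis genes fell, 34 of 41 and 38 adjusted within the list against 1 up (median -0.66), with PLK1 (-1.29), AURKA (-1.20) and MKI67 (-1.10). Adjusted p was 3.50e-17 for this list and adjusted p = 0.147 with an estimated correlation. S phase genes fell, 34 of 41 and 37 adjusted within the list (median -0.70), with the helicase subunits MCM6 (-1.14), MCM3 (-1.13) and MCM4 (-1.10) and with GINS2 (-1.11). Adjusted p was 1.20e-14 for this list and adjusted p = 0.315 with an estimated correlation. DNA repair genes fell, 14 of 26 with 2 up, 18 and 2 adjusted within the list (median -0.38), with NBN (-0.86) and XRCC2 (-0.82). Adjusted p was 0.000102 for this list and adjusted p = 0.452 with an estimated correlation. Also higher were hypoxia HIF targets (median 0.33, 18 up and 2 down of 45, 21 up and 2 down adjusted within the list), NF-kB and inflammation (median 0.26, 5 up of 25, 4 up adjusted within the list) and interferon (median 0.22, 5 up of 24, 8 up adjusted within the list), and lower was heat shock (median -0.56, 14 down of 19, 1 up and 14 down adjusted within the list). Adjusted p was 4.54e-05, 0.00419, 0.00311 and 3.18e-05 for these in order. Adjusted p = 0.534, 0.0964, 0.119 and 0.301 with an estimated correlation. In both genotypes hypoxia carried most of the HIF rise (24 h medians 1.28 WT, 1.31 KO, other stresses 0.292 at most).

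In KO cells ALDOC (5.85-fold, log2 ratio 2.55 ± 0.34), GDF15 (3.93-fold, log2 ratio 1.98 ± 0.20), NDRG1 (1.87), CCNG2 (1.68), the asparagine synthetase ASNS (1.65), KLHL24 (1.65), DDIT4 (1.62), CDKN1A (2.98-fold, log2 ratio 1.58 ± 0.15), BNIP3L (1.49) and CYP4F2 (1.46) rose most, and MRTO4 (3.19-fold lower, log2 ratio -1.67 ± 0.20), NOP56 (-1.65), the phosphodiesterase PDE4B (-1.63), RRS1 (-1.58), KITLG (-1.48), DCBLD2 (-1.48), TIMM13 (-1.40), MRPL20 (-1.39), RPUSD1 (-1.37) and SRSF2 (-1.37) fell most. Mitosis genes fell, 22 of 41, 24 down and 1 up adjusted within the list (median -0.42), with CCNB1 (-1.11), PLK1 (-1.04) and MKI67 (-0.95), and CDC25C (0.84) not passing. Adjusted p was 4.54e-05 for this list and adjusted p = 0.586 with an estimated correlation. S phase genes fell, 34 of 41 and 37 adjusted within the list (median -0.66), with GINS2 (-1.18), MCM4 (-1.13), MCM3 (-1.03) and MCM6 (-0.99). Adjusted p was 3.23e-12 for this list and adjusted p = 0.359 with an estimated correlation. DNA repair genes fell, 14 of 26 with 1 up, 15 and 1 adjusted within the list (median -0.35), with XRCC2 (-0.80) and XRCC5 (-0.78). Adjusted p was 0.000723 for this list and adjusted p = 0.534 with an estimated correlation. Also higher were hypoxia HIF targets (median 0.37, 18 up and 2 down of 45, 22 up and 3 down adjusted within the list), ATF4 and unfolded protein response (median 0.41, 13 up and 1 down of 31, 17 up and 3 down adjusted within the list), NF-kB and inflammation (median 0.26, 4 up of 25, 2 up adjusted within the list) and interferon (median 0.17, 4 up of 24, 3 up adjusted within the list), and lower were heat shock (median -0.63, 14 down of 19, also adjusted within the list) and ribosomal proteins (median -0.17, 1 up and 8 down of 49, 1 up and 6 down adjusted within the list). Adjusted p was 1.56e-06, 7.87e-06, 0.0192, 0.00888, 7.16e-05 and 0.0168 for these in order. Adjusted p = 0.434, 0.34, 0.199, 0.194, 0.333 and 0.804 with an estimated correlation. With time 5425 probes changed in WT (1555 up, 3870 down) and 5591 in KO (1873 up, 3718 down). The WT count was 3553 from condition means, and without centring the share of rises in KO moved from 33.5% to 49.9%, and with independent replicates its majority turned (6001 up, 5824 down). Other probes did not pass for NOP56 (-0.26 in WT, -0.13 in KO), TCF7L2 (-0.058), KITLG (-0.070 and -0.014 in WT, -0.26 and -0.32 in KO), MCMBP (0.15), KLHL24 (0.46) and XRCC5 (0.099 in WT, 0.069 in KO).

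The change with time itself differed between WT and KO for 2 probes, PLK2 (2.56-fold, log2 ratio 1.35 ± 0.26) and the Notch ligand DNER (2.42-fold, log2 ratio 1.27 ± 0.23), both higher in WT, with 299 at an unadjusted 0.05. The p53 targets gained more in WT, with 1 of 81 past the test and 16 adjusted within the list (median 0.31), and AEN (0.97), TRIAP1 (0.91) and DDB2 (0.89) did not pass. Adjusted p was 1.12e-43 for this list and adjusted p = 6.55e-07 with an estimated correlation. Also higher were ribosomal proteins (median 0.058, 0 of 49 passed), with RPL10A (0.50), RPL13 (0.23), RPS15 (0.17) and RPL38 (0.17). Adjusted p was 0.0032 for this list and adjusted p = 0.769 with an estimated correlation. Lower lists were mitosis and G2/M (median -0.30, 0 of 41 passed), NRF2 and oxidative stress (median -0.14, 0 of 28 passed) and ATF4 and unfolded protein response (median -0.15, 0 of 31, 3 down adjusted within the list). Adjusted p was 1.75e-21, 0.0323 and 1.07e-10 for these in order. Adjusted p = 0.0926, 0.756 and 0.0972 with an estimated correlation. Their largest members were AURKA (-0.51), NEK2 (-0.50), CENPF (-0.49), CCNF (-0.48), GCLC (-0.69), GPX1 (0.47), SLC7A11 (-0.39), HMOX1 (-0.35), ASNS (-1.18), TRIB3 (-0.65), AARS1 (-0.62) and SLC7A5 (-0.60). The count was 14 without WT hypoxia 24 h replicate 4, 5 without replicate 1 of that condition, 4 after scaling, 0 from condition means and 273 with independent replicates, where the majority turned (113 higher, 160 lower).

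The metallothionein and zinc list (5 genes) and the markers of fibroblasts and leukocytes (13 genes) passed in 0 comparisons by cameraPR, with medians over all stresses of 0.029 and 0.048 in WT minus KO. By fry the markers passed in WT NO, WT and KO hypoxia and 24 h against 1 h in WT and KO (medians 0.057 to 0.25, adjusted p = 0.00581 to 0.0318). With members on 80% of arrays, 24 h against 1 h in WT passed (cameraPR, adjusted p = 0.0496). In all, 112 of 240 list tests passed, and 24 with an estimated correlation.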

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

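The 90 tests of list differences between stresses were chosen after the data were seen, the others before. Arrays far from the others of their condition were sought in 111 tests over 6 conditions, and chance alone gives about 1 in 20. In WT hypoxia 24 h, replicate 4 had a median of 0.47 for the ATF4 and unfolded protein response list (others 0.76 to 0.82), and replicate 5 had -0.033 for the interferon list (others 0.13 to 0.20). WT H2O2 24 h replicate 3 had values for 18891 probes (others 20610 to 20874). KO H2O2 24 h replicate 3 had an SD of 0.58 (others 0.29 to 0.36).

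WT and KO differed over all stresses in 62 probes. Of 100 swaps of WT and KO labels within pairs of conditions, 1, the real one, gave as many, and the highest other gave 52, so chance can be excluded at a share of 5%. Per stress the 4 swaps are too few for such a share. The real and the highest other counts were 14 and 14 for NO, where 2 swaps gave as many, and 4 and 0 for H2O2, 5 and 1 for HU and 6 and 0 for hypoxia, where 1 did. For the F test of the difference between stresses the real count was 0 (250 at an unadjusted 0.05, limma), which all 100 of 100 assignments reach, so the comparison decides nothing. The 8 swaps of time are too few as well. The real and the highest other counts were 5425 and 2137 in WT, 5591 and 1444 in KO, and 2 and 1 for WT against KO, with 1 swap as large in each.

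The WT minus KO value of 2 lists differed between stresses with an estimated correlation, adjusted over 90 tests. The immediate early list was higher in NO than in H2O2 by a median of 0.38 (adjusted p = 0.00527, cameraPR) and lower in H2O2 than in hypoxia by -0.47 (adjusted p = 0.00527, cameraPR). Cholesterol synthesis was higher in H2O2 than in HU by 0.30 (adjusted p = 0.0446).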

How the results depend on the processing

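The tests of later times minus 1 h, without 1 h, without the 4 low-correlation arrays and with repeated control rows kept were chosen after seeing the data, the others before. "Time" is 24 h against 1 h, "p53 in" a stress is WT minus KO there, and the cause of each change was not tested, beyond what the setting itself does. Counts stayed within 1.5 times of their value with no centring, values on 80% of arrays, no filter, control rows kept and without the low-correlation arrays. Array weights were estimated gene by gene after the first method had stopped short of convergence and its counts had been seen.

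From condition means, counts were 13 for p53 status, 0 for p53 in NO, H2O2, HU and hypoxia each, 877 for WT NO, 5 for WT H2O2, 47 for WT HU, 442 for KO NO, 1 for KO H2O2, 39 for KO HU, 3553 for time WT and 0 for time by p53. With arrays as independent replicates, counts were 1102 for p53 status and 683, 81, 365 and 825 for p53 in NO, H2O2, HU and hypoxia. For NO, H2O2 and HU they were 7287, 2290 and 4851 in WT and 8102, 1851 and 3818 in KO. Time WT gave 11903, time KO 11825, time by p53 273 and the F test 663. After scaling to one spread, counts were 135 for p53 status and 4, 28, 81 and 0 for p53 in NO, H2O2, HU and hypoxia. For H2O2, HU and hypoxia they were 1542, 2929 and 4905 in WT and 1447, 2906 and 4726 in KO. Time by p53 gave 4 and the F test 1. With array weights, counts were 259 for p53 status and 49, 18, 173 and 10 for p53 in NO, H2O2, HU and hypoxia. For NO, H2O2 and HU they were 4400, 639 and 2352 in WT and 3896, 361 and 3970 in KO. Time by p53 gave 47 and the F test 2. With the hybridisation block as a term, counts were 31 for p53 in NO, 3789 for WT NO, 418 for WT H2O2, 1511 for WT HU, 325 for KO H2O2, 917 for KO HU and 4 for time by p53. With trended and robust moderation, counts were 41 for WT H2O2 and 21 for KO H2O2. With a 1.5-fold cut-off as well, counts were 15 for p53 status, 1827 for time WT and 1923 for time KO. For NO, H2O2, HU and hypoxia they were 455, 25, 118 and 2611 in WT and 259, 20, 98 and 2282 in KO. From 24 h alone, counts were 1428 for p53 status and 264, 565, 238 and 1238 for p53 in NO, H2O2, HU and hypoxia. In that order they were 5913, 5941, 4384 and 14625 in WT and 3934, 7041, 3832 and 13365 in KO. There arrays were the replicates. Against the other 3 stresses, counts were 0 for p53 in NO, H2O2, HU and hypoxia each, 669 for WT NO, 129 for WT H2O2, 1046 for KO NO, 335 for KO HU and 5133 for KO hypoxia. From later times minus 1 h, counts were 6 for p53 status. Without the 1 h conditions, counts were 200 for p53 status and 84, 20, 21 and 38 for p53 in NO, H2O2, HU and hypoxia. For NO, H2O2 and HU they were 5519, 215 and 2300 in WT and 4573, 348 and 1595 in KO. The F test gave 8. Of 240 list tests, 24 passed with an estimated correlation and 69 by fry, against 112 by cameraPR.

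Leaving out 1 array at a time gave 52 to 83 for p53 status, 4843 to 6335 for time WT and 4846 to 6275 for time KO. It gave 2 to 14 for time by p53 and 0 for the F test. For p53 in NO, H2O2, HU and hypoxia it gave 11 to 21, 4 to 5, 5 to 8 and 4 to 34. In that order WT gave 1928 to 2760, 40 to 92, 590 to 977 and 7743 to 8610. KO gave 1140 to 2515, 27 to 54, 336 to 657 and 7164 to 8326.

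After scaling to one spread, the sign turned for TXNRD1 (-0.010) in p53 in NO, CDKN1A (-0.045) in p53 in HU. With array weights, the sign turned for TXNRD1 (-0.031) in p53 in NO, RRM2 (-0.10) and PLK1 (0.087) in p53 in HU, GCLM (-0.025) in WT H2O2, RPL13 (-0.052) in time by p53. With the hybridisation block as a term, the sign turned for DDX46 (0.061) in KO NO, STC2 (-0.20) in KO H2O2. From 24 h alone, the sign turned for SCD (-0.025) in p53 status, HMOX1 (-0.16) and TXNRD1 (-0.28) in p53 in NO, FOS (0.19) and GDF15 (-0.12) in p53 in H2O2, IL1A (-0.085) and CDKN1A (-0.15) in p53 in HU, CDKN1A (-0.47), MDM2 (-0.17), TP53I3 (0.19) and VEGFA (-0.046) in p53 in hypoxia, TXNRD1 (-0.20) and GCLM (-0.38) in WT H2O2, GCLM (-0.067) and EGR1 (-0.21) in KO H2O2. Against the other 3 stresses, the sign turned for FOS (-0.003) in p53 in NO, PLK2 (-0.34), PPM1D (-0.037), TP53INP1 (-0.075), DLGAP5 (0.048), HMMR (0.057), STARD4 (-0.009), INSIG1 (-0.011), GDF15 (0), BBC3 (-0.24) and EGR1 (-0.26) in p53 in H2O2, PLK2 (-0.054), SESN1 (-0.22), AKR1B10 (-0.12), CDKN1A (-0.35), MDM2 (-0.063) and BBC3 (-0.21) in p53 in HU, PLK2 (-0.016), CENPF (0.28), CDKN1A (-0.005), MDM2 (-0.48), SESN1 (-0.18), PPM1D (-0.32) and NDRG1 (0.023) in p53 in hypoxia, GDF15 (-0.16), SFN (-0.046), PLK2 (-0.25), GADD45A (-0.30), CCN1 (-1.03), SESN1 (-0.064), MAFF (-0.73), DDX46 (0.23), H3C12 (1.27), DLGAP5 (0.24), KIF23 (0.11), FAM83D (0.20), AURKA (0.27), GINS2 (0.13), SLBP (0.28), MCM6 (0.15), POLE2 (0.25), HSPA1B (0.44), DNAJB1 (0.14), HSPA1A (0.44), PPP1R15A (-0.62), HMOX1 (-1.08), TXNRD1 (-0.39), GCLM (-0.56), FOS (-0.26) and EGR1 (-0.38) in WT H2O2, GDF15 (-0.63), CDKN1A (-0.082), CCN1 (-0.81), CCN2 (-0.30) and MAFF (-0.94) in WT HU, H3C12 (0.086) in WT hypoxia, DDX46 (0.32), NDRG1 (-0.33) and ALDOC (-0.053) in KO NO, DDIT4 (-0.48), GDF15 (-0.16), GADD45A (-0.071), CDKN1A (-0.072), AIMP1 (0.052), BTG1 (-0.17), AURKA (0.13), CCNF (0.087), HSPA1B (0.32), HSPA1A (0.26), DNAJB1 (0.25), HSPA8 (0.17), DDIT3 (-0.18), HMOX1 (-1.02), TXNRD1 (-0.34), GCLM (-0.43) and EGR1 (-0.12) in KO H2O2, SFN (-0.12), GADD45A (-0.43), ALDOC (-0.37), NDRG1 (-0.78), BHLHE40 (-0.64), DDIT4 (-1.16) and CCNB1 (0.060) in KO HU. From later times minus 1 h, the sign turned for DBP (0.029), NR1D1 (0.13), NR1D2 (0.45), TEF (0.28), INSIG1 (-0.066), SCD (-0.048), RPL28 (-0.006) and CDKN1A (-0.023) in p53 status. Without the 1 h conditions, the sign turned for CDKN1A (-0.092) in p53 in HU, FAS (0.016) in p53 in hypoxia, GCLM (-0.012) in WT H2O2. Without the low-correlation arrays, the sign turned for IL1A (-0.004) in p53 in HU. With 1 array left out, values ranged for HMOX1 (-0.14 to 0.014) in p53 in H2O2 and TXNRD1 (-0.074 to 0.11) in p53 in NO. In p53 in hypoxia they ranged for LDHA (-0.13 to 0.029), NDRG1 (-0.23 to 0.053), FAS (-0.074 to 0.010) and MDM2 (-0.022 to 0.14).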

Other observations

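The tests of patterns below were chosen after their results were seen, except those of hybridisation blocks and of gene length. Lists had their own course in time, given as the mean over arrays of the list median. HIF targets stood at 0.12 ± 0.10 (SD, n = 3) after 1 h of hypoxia in WT, 1.54 ± 0.011 (SD, n = 2) after 12 h and 1.28 ± 0.34 (SD, n = 5) after 24 h, and in KO at 0.14 ± 0.047 (SD, n = 3), 1.19 ± 0.15 (SD, n = 3) and 1.31 ± 0.17 (SD, n = 3). Under NO they stood highest at 8 h, at 0.59 ± 0.19 (SD, n = 3) in WT and 0.47 ± 0.15 (SD, n = 2) in KO, against 0.18 ± 0.14 (SD, n = 3) and 0.29 ± 0.071 (SD, n = 3) at 24 h. NRF2 and oxidative stress genes stood at 0.78 ± 0.19 (SD, n = 3) after 8 h of NO in WT and 0.33 ± 0.060 (SD, n = 2) in KO, and at 0.66 ± 0.14 (SD, n = 3) and 0.64 ± 0.10 (SD, n = 3) after 24 h. Mitosis genes stood at 0.019 ± 0.23 (SD, n = 2) after 12 h of hypoxia in WT and -0.82 ± 0.16 (SD, n = 5) after 24 h. These differences between times within a stress were not tested.

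DBP, NR1D1, NR1D2 and TEF lay lower in WT than in KO arrays, by a mean of -0.82 at 1 h (SD 0.37 over 4 stresses, below 0 in 4 of 4) and -0.93 at 24 h. The block of hybridisation numbers is argued against, since the difference stayed below 0 in every block (highest -0.27), and so is a constant offset of the untreated reference as the whole cause in NO, HU and hypoxia, since the difference moved by 0.67 (SD 0.17) from 1 h to 8 or 12 h. It stays open for H2O2, where the difference moved by 0.26 (SD 0.061 over 4 genes) to 4 h. A difference between the untreated references of the genotypes may account for the value at 1 h (-0.82). A p53-dependent change that grows during stress stays open, since the change from 1 h to 24 h was -0.11 (SD 0.18, further below 0 in 3 of 4 stresses). A different clock phase of the cultures also stays open, since WT minus KO of 5 other clock genes at 1 h and 24 h lay by -0.41 from that at 8 or 12 h on average over NO, HU and hypoxia, not past the set bound in each.

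GOLGB1, AKAP9, GOLGA4, DST, CEP290, CENPE and CENPF lay above 0 in KO HU arrays at each time (1.00, 1.02 and 1.01), and at 0.45 in WT HU at 1 h. A bias with genomic length is argued against by the longest of the other genes, which had a median of -0.019 in KO HU. Only 2 of the 7 are that long, and transcript length is open. A single untreated KO reference common to all stresses is argued against by the mean of -0.046 at 1 h in KO NO. An offset of the HU arrays, or of a reference of their own, may account for the HU values, since the mean at 1 h was already 1.00, but leaves out KO H2O2, where the means were 0.72, 0.49 and 0.58 at 1, 4 and 24 h. A response complete within 1 h, as a biological explanation, was not tested.

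The median of 30 replication-dependent histone genes at 1 h was -0.24 in WT and -0.14 in KO under NO, and -0.35 and -0.46 under HU. At 24 h it was 0.014 and 0.10 under NO and -0.44 and -0.21 under H2O2. The mean in H2O2 and hypoxia at 1 h was -0.003, but the grouping was chosen after seeing it, so a dye effect of the probes stays open. So does an untreated reference of 1 genotype, with the higher of both medians -0.35 for HU and -0.14 for NO. At 1 h the 4 NO and HU conditions all lay below the 4 H2O2 and hypoxia conditions (exact permutation p = 0.0286, 2-sided, the smallest the design allows), but genes and grouping were chosen after these values were seen, and it fails at 24 h, so this is no support for a response to NO and HU, which stays open.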
